A study of Homo sapiens with 6 samples.

How the data were processed

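RNA sequencing of MDA-MB-231 cells with a control hairpin (3 libraries) or a PML hairpin (3 libraries) was analysed from the table of whole-number counts per gene symbol that the authors deposited. Per the labels' protocols, hairpins were delivered by lentivirus, total RNA was isolated with a column kit, and libraries were made with a stranded protocol that selects polyadenylated RNA. The submitters' processing notes name Trimmomatic 0.39, STAR 2.5.3a, featureCounts 1.6.4 and DESeq2, and the builds GRCh38 and hg38, without giving the role or settings of each. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of genes that overlap on opposite strands can be told apart only if the counting used strand. Of the 25 genes named for the largest change or as the target, 13 share exon positions with an annotated gene on the opposite strand, among them PML, TP53I11, NEBL, SPARC, TNC and CTSW. Of the same 25, 3 (SERPINB2, SYT16 and CD22) share exon positions with another gene on the same strand, which use of strand would not resolve. The treatment of reads that map to several places is likewise not given, so near-identical relatives such as the ribosomal protein genes and their processed copies can share or lose reads.

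The deposited counts were used as they stand, with 56832 symbols and 6 columns, each matched to 1 library by its description; 0 columns of per-sample values were left unused. Library totals were 30.7 M to 42.5 M counted reads (M, 1e6 reads), and a library's own counting error is small beside the spread between libraries for all but the lowest genes. Groups and replicate numbers were taken from the sample titles. The labels do not state that the replicates came from separate cultures or infections, so p-values measure only the spread between these samples, which can be technical. No libraries of a group were duplicates: chi-square per degree of freedom between libraries of a group was 34.5 to 219.

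Symbols were matched to GENCODE release 44 on GRCh38, the build named in the submitters' notes, directly (27141) or through older symbols in a RefSeq gene table (1428); 202 matched several genes and 28061 none. All members of the gene lists were found. Matched genes gave coordinates, transcript length, GC content and 3′ UTR sequence. Length and GC content are those of the gene's longest annotated transcript, which can differ from the transcript sequenced. The 3′ UTR is the longest one annotated for the gene.

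The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with group as the only term, filterByExpr (minimum count 10, minimum total 15), TMM scaling, robust dispersion estimates and Benjamini-Hochberg adjustment over the 16232 genes kept, at an adjusted p under 0.05. Log2 fold changes are knockdown over control, the SE is the fold change over the square root of the F statistic, and CPM values are TMM-scaled. Gene lists were tested with limma's camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 28 of 30 lists with at least 5 members kept, and beside it with an estimated correlation and with fry. Members of each list were counted over all genes tested and adjusted over the list alone. The groups, main test, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names PML, the 12 genes with the largest rise and the 12 with the largest fall among those with a symbol (clone names not counted), an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups' CPM, and up to 4 members with the smallest p for each list; 1 of the 24 genes of largest change is not reported here, though counts over the 24 include it. Further members named in the report (LAMA4, COL6A3, HBEGF, HLA-DPA1 and HLA-DMA) and the genes outside the lists in the closing section were chosen after their values were seen.

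The titles number the replicates 1 to 3 in both groups. Deviations from the group means correlated by 0.51, 0.41 and 0.19 between same-numbered libraries, each above the 0.1 set beforehand, and between -0.44 and 0.15 for other numbers. The 0.15, of control replicate 1 with knockdown replicate 3, also lay above 0.1 and near the 0.19 of pair 3. The bound alone thus does not part same-numbered libraries from others, and pair 3 is the least set apart. With this limit the numbers were taken to pair the libraries. Values from the fit with the replicate number as a block are given where they change the call of a list or of a gene named here. They are also given where they change a list's count of members that passed. The pairing rests on the titles and this check; no label says what a number stands for. The common biological coefficient of variation was 0.232 without and 0.168 with the block.

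The test was run on simulated data for this comparison, with counts drawn for the 16232 genes and 100 genes changed at each fold size. Without the block it recovered 36% of genes changed 2-fold and 89% of those changed 4-fold, with 15 false calls in all. The run with the block drew other counts, with an effect of each replicate number added and a lower dispersion. It recovered 66% and 95%, with 6 false calls, so these runs do not measure a gain from the block. Changes of about 2-fold can therefore be missed at this depth and number of libraries.

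Alternatives fixed in advance were DESeq2 1.42.0, without and with the block; limma-voom; DESeq2 size factors, library sizes and upper-quartile factors in edgeR; no filter beyond 1 read and a filter of 1 CPM in 3 libraries; the replicate block; and each library left out in turn. Fits with each library's trends with transcript length and GC content removed (lowess, span 0.3), and with each pair left out under the block, were added after the data were seen, as was the estimated correlation in fits other than the main and the blocked one. The 3′ UTR search used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1: for each of 16345 sequences of 7 bases, a linear model over 12856 genes related its presence to the log2 fold change (trends removed, block kept), with UTR length and GC content as covariates.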

Results

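Polyadenylated RNA was sequenced from MDA-MB-231, an established human cell line of triple-negative breast cancer (a breast cancer without oestrogen receptor, progesterone receptor or HER2 amplification). The cells carried a lentiviral short hairpin RNA, a precursor of a small RNA that silences transcripts it pairs with, directed either at PML or at no named target (the control hairpin). Each of the 2 groups had 3 libraries numbered 1 to 3. Control replicates 1, 2 and 3 held 38.6 M, 42.5 M and 40.1 M counted reads (M, 1e6 reads). PML knockdown replicates 1, 2 and 3 held 30.7 M, 32.7 M and 39.6 M. PML knockdown replicate 2 stood apart from the other 5 libraries along the first principal component, which held 52.4% of the variance, at 75.5 against a range of -47.4 to 6.8. In that library short transcripts had higher and long transcripts lower values than the 6-library mean, by 0.46 and -0.54 log2 units for the shortest and the longest of 5 length classes of genes, as the plot of expression by transcript length shows. Its Spearman correlation across genes between transcript length and deviation from that mean was -0.57, against 0.05 to 0.37 in the other 5 libraries (genes are not independent replicates). Control replicate 1 had the strongest trend with GC content, with a Spearman correlation across genes of -0.61, against -0.27 to 0.38 in the other libraries.

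PML, the gene whose product is the scaffold of PML nuclear bodies, fell in the knockdown libraries and was lower in all 3 of them than in any control. The gene lies on chromosome 15 at 73994673 to 74047827 (GRCh38). It had 1945, 2217 and 2622 reads in control replicates 1, 2 and 3 and 739, 671 and 1034 reads in knockdown replicates 1, 2 and 3. Its level was 55.0 ± 8.59 CPM in control and 24.0 ± 1.95 CPM in knockdown (mean ± SD, n = 3), which is 2.29-fold lower, a log2 fold change of -1.20 (SE 0.19, adjusted p = 0.0179 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The knockdown libraries thus kept 0.437 of the control level. With 1 library left out, PML no longer passed in 5 of the 6 fits. Its adjusted p was 0.0727, 0.0743 and 0.112 without control replicates 1, 2 and 3, and 0.0544, 0.0044 and 0.0603 without knockdown replicates 1, 2 and 3. These fits have no block. With the replicate block its adjusted p by edgeR was 0.00687. It was 0.00241, 4.03e-09 and 0.00211 with the block and pair 1, 2 or 3 left out, at 1 residual degree of freedom.

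The only comparison the design gives, knockdown against control, asks which transcripts depend on PML in these cells, with genes tied to metastasis as the study's stated interest. Among genes with a mean log2 CPM of at least 1, the largest rises were in PDGFB, a platelet-derived growth factor chain, from 2.29 ± 0.36 to 26.7 ± 2.10 CPM (mean ± SD, n = 3, 11.7-fold), and in CLDN1, a tight junction claudin, from 3.18 ± 0.16 to 24.2 ± 10.5 CPM (7.61-fold). At that level of expression the largest falls were in SERPINB2, an inhibitor of plasminogen activators, from 8.88 ± 2.84 to 0.41 ± 0.19 CPM (21.1-fold), and in TIE1, a receptor tyrosine kinase of endothelium, from 3.67 ± 1.84 to 0.22 ± 0.05 CPM (16.0-fold). TNC, the matrix glycoprotein tenascin-C, fell from 89.6 ± 10.1 to 17.4 ± 4.92 CPM, and CD74, the invariant chain of MHC class II, fell from 20.1 ± 6.34 to 3.41 ± 0.17 CPM. Of 16232 genes tested, 204 rose and 210 fell at an adjusted p under 0.05 (edgeR's quasi-likelihood test), 181 and 170 of them by at least 2-fold. An unadjusted p under 0.05 was reached by 2769 genes. With the replicate number as a block, 636 genes rose and 686 fell, among them all 414 of the unblocked test. The CPM of the groups did not overlap for 25.4% of the genes tested, where chance gives 10%.

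**Figure D1:**
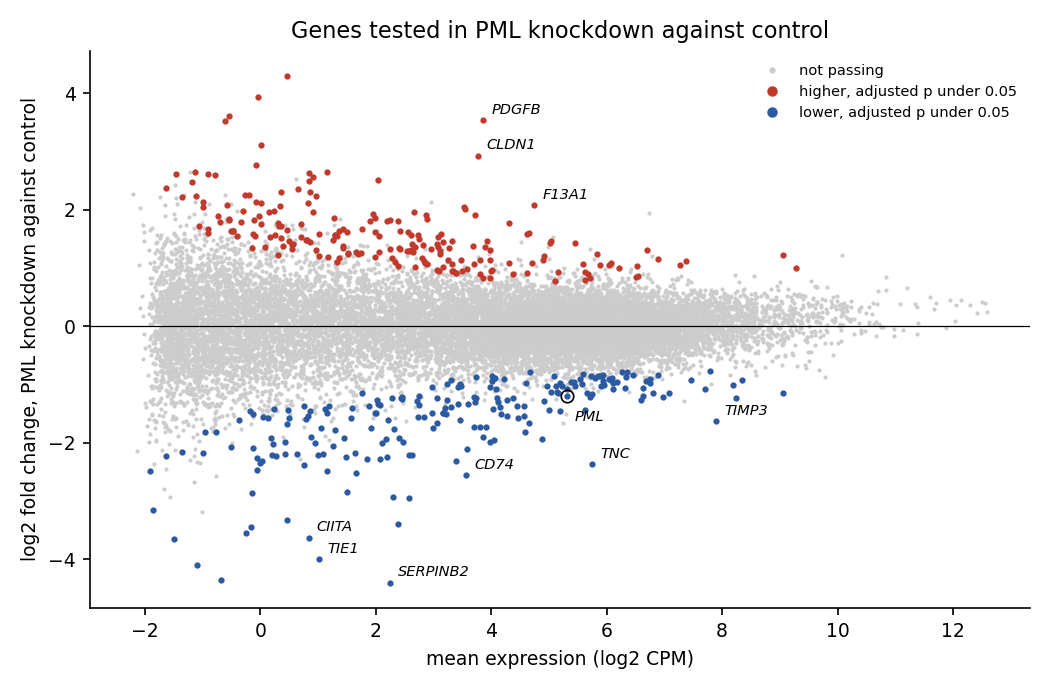
Log2 fold change of PML knockdown against control (vertical axis) by mean expression (horizontal axis, log2 CPM) for the 16232 genes tested. Red points are the 204 genes that rose and blue points the 210 that fell at an adjusted p under 0.05; the circle marks PML at -1.20.

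Among the 12 genes with the largest rise at a mean log2 CPM of at least 1, after PDGFB (log2 fold change 3.54, SE 0.22) and CLDN1 (2.93, SE 0.32) came KCNJ12, an inwardly rectifying potassium channel (2.64, SE 0.30), and TP53I11 (2.51, SE 0.31). F13A1, the catalytic subunit of coagulation factor XIII, was the most abundant of the 12 in the knockdown, with 10.2 ± 3.20 CPM in control and 43.2 ± 20.2 CPM in knockdown (log2 fold change 2.08). They were followed by SEC14L6, DBNDD1, the adhesion receptor ADGRA2, NEBL, LRRC75A and TTC9, with log2 fold changes of 1.90 to 2.05. Among the 12 with the largest fall at that level, SERPINB2 (-4.40, SE 0.41) and TIE1 (-4.00, SE 0.51) were followed by IGFN1 (-2.95), the smooth muscle actin gene ACTG2 (-2.93), FSIP2 (-2.84) and CD74 (-2.56). SPARC, a matricellular protein, fell by 2.52 on the log2 scale, from 5.23 ± 2.91 to 0.91 ± 0.02 CPM, and TNC by 2.36. SYT16, the B-cell lectin CD22, the protease gene CTSW and the thrombin receptor gene F2RL2 had log2 fold changes of -2.48 to -2.27. Adjusted p of these 24 genes lay between 5.22e-04 and 0.0485 by edgeR's quasi-likelihood test. Each went the same way in all 3 pairs of same-numbered libraries, but the rule of no overlap between the groups' CPM fixes this in advance. KCNJ12 and ACTG2 have near-identical relatives, so their counts are uncertain to that extent. Without control replicates 1, 2 and 3, 19, 4 and 23 of the 24 no longer passed, and without knockdown replicates 1, 2 and 3, 5, 1 and 5 no longer passed. None changed direction, which the same rule largely fixes. The number of genes that passed in those 6 fits was 11, 90 and 3 without control replicates 1, 2 and 3, and 144, 1116 and 72 without knockdown replicates 1, 2 and 3. With the replicate block and pair 1, 2 or 3 left out, at 1 residual degree of freedom, all 24 passed. They were chosen for passing in these same libraries, so this is not separate support.

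**Figure D2:**
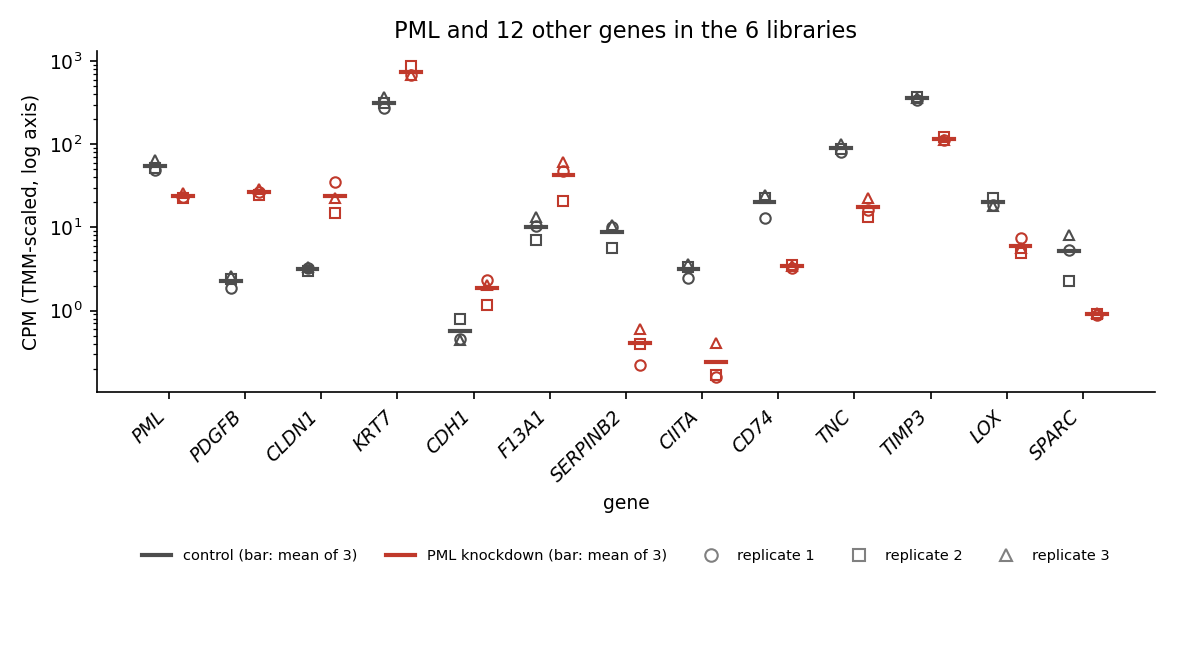
TMM-scaled CPM (vertical axis, log scale) of PML and 12 other genes (horizontal axis) in each library. Grey symbols are control and red symbols PML knockdown libraries, with a bar at the mean of 3; for every gene shown the 3 knockdown values lie on one side of the 3 control values, as for PML (22.3 to 26.1 against 48.9 to 64.8 CPM).

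The list of extracellular matrix and protease genes had a median log2 fold change of -0.59 in the knockdown, with 28 of 34 values below 0 (adjusted p = 3.08e-06 by limma's camera with a preset correlation; adjusted p = 0.711 with an estimated correlation). TIMP3, an inhibitor of metalloproteinases and the most abundant of the members that passed, fell from 358 ± 15.4 to 116 ± 5.81 CPM (log2 fold change -1.63, SE 0.16), and LOX, which crosslinks collagen, fell from 20.0 ± 2.55 to 6.04 ± 1.31 CPM (-1.72, SE 0.22). MMP3, a secreted metalloproteinase, fell from 3.76 ± 0.62 to 0.91 ± 0.28 CPM. TNC, SPARC, the laminin gene LAMA4 (-1.60) and the collagen gene COL6A3 (-1.99) completed the 7 of 34 members that fell; none rose. Adjusted over the list alone, 14 fell and 2 rose, and with the replicate block 10 fell and 2 rose. Without control replicates 1, 2 and 3, 2, 6 and 0 members fell, and without knockdown replicates 1, 2 and 3, 5, 10 and 3 fell, with 2 that rose without knockdown replicate 2. The list's medians in pairs 1, 2 and 3 were -0.42, -0.52 and -0.48.

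The list of genes tied to lung and bone metastasis in breast cancer models had a median of -0.47 (adjusted p = 0.00884 by camera; adjusted p = 0.582 with an estimated correlation). ADAMTS1, a matrix protease, fell from 38.2 ± 2.47 to 12.1 ± 1.61 CPM (log2 fold change -1.66, SE 0.19), and EREG, a ligand of the EGF receptor, fell from 13.7 ± 2.71 to 4.82 ± 1.56 CPM (-1.51, SE 0.28). TNC, SPARC and the EGF receptor ligand HBEGF (-0.97) made up the other 3 of the 5 members that fell, of 22 tested; none rose. Adjusted over the list alone, 7 fell and 4 rose, and with the replicate block 7 fell and 3 rose. Without control replicates 1, 2 and 3, 1, 3 and 0 members fell, and without knockdown replicates 1, 2 and 3, 3, 7 and 2 fell, with 1 that rose without knockdown replicate 2. The median was -0.39, -0.05 and -0.59 in pairs 1, 2 and 3. The list shares 3 tested members with the matrix list.

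The epithelial list had a median of 0.67, with 16 of 18 values above 0 (adjusted p = 2.63e-06 by camera; adjusted p = 0.582 with an estimated correlation). CLDN1 rose as given above, KRT7, a keratin of simple epithelia, rose from 318 ± 49.2 to 746 ± 107 CPM (log2 fold change 1.23, SE 0.20), and CDH1, the E-cadherin gene, rose from 0.56 ± 0.19 to 1.86 ± 0.62 CPM (1.72, SE 0.37), a low level in both groups. These were the 3 of 18 members that rose, and 9 rose when adjusted over the list alone and 4 with the replicate block; none fell. Without control replicates 1, 2 and 3, 0, 1 and 0 rose, and without knockdown replicates 1, 2 and 3, 2, 8 and 1 rose. The mesenchymal list had a median of -0.42 and was lower by camera (adjusted p = 0.0212; adjusted p = 0.582 with an estimated correlation), but none of its 17 members passed on its own and 1 fell when adjusted over the list alone, 3 with the block and 2 without knockdown replicate 2. SNAI2, a repressor of E-cadherin, had a log2 fold change of -0.84 (SE 0.19, adjusted p = 0.0522 by edgeR; 0.0169 with the replicate block), and ZEB2 had -0.80 (adjusted p = 0.132; 0.0356 with the block). Without control replicate 3 the adjusted p of the mesenchymal list by camera was 0.130. The mesenchymal list shares 3 tested members with the matrix list.

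Cholesterol biosynthesis genes were higher, with 23 of 24 members above 0 and a median of 0.51 (adjusted p = 1.75e-06 by camera; adjusted p = 0.582 with an estimated correlation). TM7SF2, a sterol reductase, rose from 5.86 ± 1.02 to 11.9 ± 1.55 CPM (log2 fold change 1.02, SE 0.22) and was the only member that passed. It shares exon positions with VPS51 on the same strand, so its counts are uncertain to that extent. When adjusted over the list alone 6 rose, and with the replicate block 8 rose, the mevalonate pathway enzymes MVD (0.92) and MVK (0.99) in both counts. Without knockdown replicate 2, 5 rose, without control replicate 2, 1 rose, and without any 1 of the other 4 libraries none rose. The medians were 0.89, 0.22 and 0.76 in pairs 1, 2 and 3. All 29 genes of autophagy and the lysosome lay above 0, with a median of 0.26 (adjusted p = 0.00149 by camera; adjusted p = 0.582 with an estimated correlation), and none passed on its own or adjusted over the list alone, while 2 rose with the block and 1 without knockdown replicate 2. ULK1, a kinase that starts autophagy, had the smallest p of them (log2 fold change 0.83, SE 0.20, adjusted p = 0.0612 by edgeR; 0.0172 with the block).

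The 48 cytosolic ribosomal protein genes had a median of 0.35 (adjusted p = 0.0320 by camera; adjusted p = 0.811 with an estimated correlation), but the pairs differed. Their medians in pairs 1, 2 and 3 were -0.05, 0.79 and -0.02, and without knockdown replicate 2 the median was -0.18 and the list was lower (adjusted p = 0.0275 by camera; adjusted p = 0.885 with an estimated correlation). It also lost its call without control replicate 1 (adjusted p = 0.277) and without control replicate 3 (adjusted p = 0.217). No member passed on its own or adjusted over the list alone. By the longest annotated transcript of each gene, the list's median length, 2040 bases, lay below that of all genes tested, 3821 bases. Nuclear-encoded genes of oxidative phosphorylation had a similar pattern, with medians of -0.04, 0.63 and -0.02 in pairs 1, 2 and 3 and no call over all libraries (median 0.27, adjusted p = 0.138 by camera). They were called higher by camera without control replicate 2 (adjusted p = 0.0316) and without knockdown replicates 1 (0.00594) and 3 (0.00804), where the adjusted p was 0.825, 0.813 and 0.776 with an estimated correlation. Their direction turned without knockdown replicate 2 (median -0.09, adjusted p = 0.157 by camera) and with the block and pair 2 left out (median -0.02, adjusted p = 0.724). The 13 mitochondrially encoded mRNAs had a median of 0.38 (adjusted p = 0.138 by camera) and were called higher with the replicate block (adjusted p = 0.0143), with trends removed and the block (0.00864), with the block and pair 2 left out (0.0141), without control replicate 3 (0.00609) and without knockdown replicate 2 (0.00849). In these 5 fits the adjusted p was 0.715 to 0.874 with an estimated correlation. The median was only 0.08 without control replicate 2 (adjusted p = 0.854 by camera) and 0.02 without knockdown replicate 3 (adjusted p = 0.654). The share of reads from all symbols that start with MT-, not limited to these mRNAs, was 3.23%, 1.78% and 4.27% in control replicates 1, 2 and 3. It was 3.66%, 2.55% and 5.54% in knockdown replicates 1, 2 and 3.

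**Figure D3:**
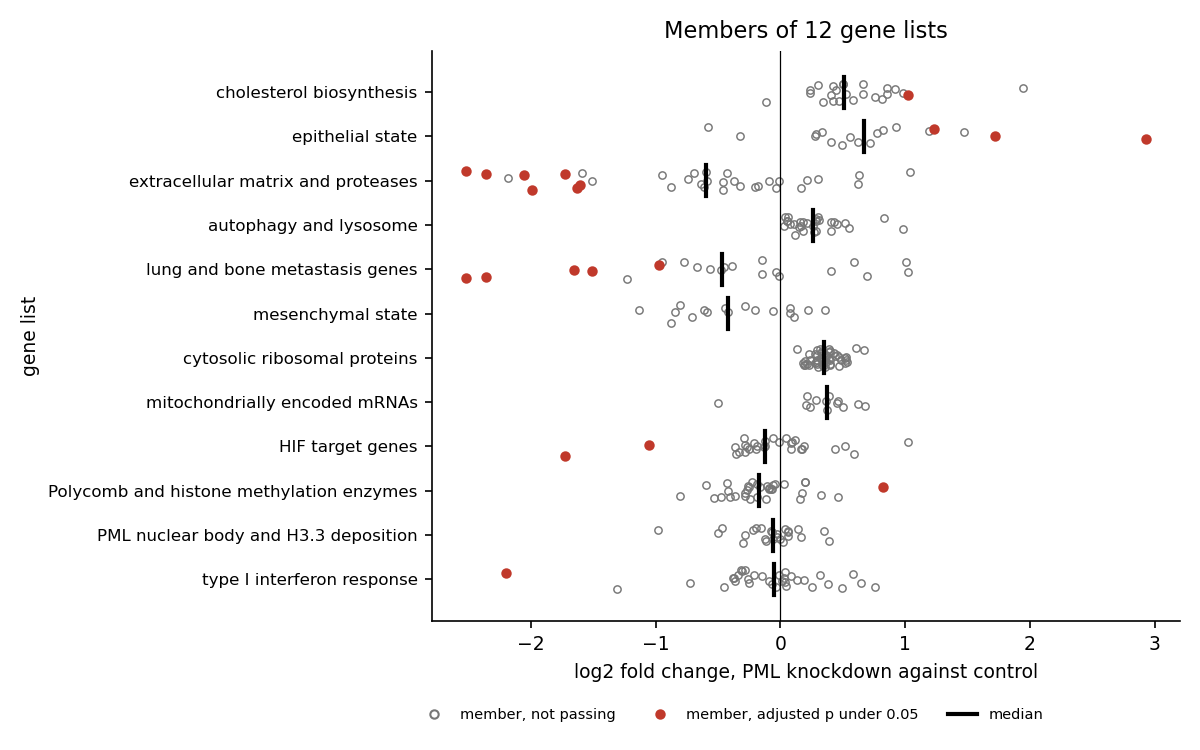
Log2 fold change of PML knockdown against control (horizontal axis) for each tested member of 12 gene lists (vertical axis), the 7 that camera called and 5 others. Filled red points passed at an adjusted p under 0.05, open points did not, and black bars are medians, from -0.59 for the matrix list to 0.67 for the epithelial list.

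The antigen presentation list as a whole was not called (median -0.09, adjusted p = 0.289 by camera). Among its members CIITA, the transactivator of class II genes, fell from 3.15 ± 0.63 to 0.24 ± 0.14 CPM (log2 fold change -3.63, SE 0.40), CD74 fell as given above, and HLA-DRA, a class II chain, fell from 0.74 ± 0.04 to 0.04 ± 0.08 CPM. The other class II genes of the list, HLA-DPA1 (-1.17, adjusted p = 0.320 by edgeR) and HLA-DMA (-0.68, adjusted p = 0.247), did not pass. HLA-F, a class I gene, rose (1.24, SE 0.24), so that 3 of 23 members fell and 1 rose; adjusted over the list alone, and also with the block, 4 fell and 1 rose. Without control replicates 1, 2 and 3, 2, 2 and 0 members fell, and without knockdown replicates 1, 2 and 3, 2, 4 and 2 fell, with 1 that rose without knockdown replicate 2 and none in the other 5 fits.

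In the NF-kB list the leukocyte adhesion gene ICAM1 rose (log2 fold change 1.25, SE 0.22), and the cytokine genes IL1A (-2.23, SE 0.41) and CXCL8 (-1.22, SE 0.24) fell. The list was not called (median -0.33, adjusted p = 0.126 by camera). Adjusted over the list alone, and also with the block, 2 rose and 5 fell of 24. Camera called it lower without control replicate 1 (adjusted p = 0.0484), without control replicate 2 (0.0220), with the stricter filter (0.0419), with trends removed and the block (0.0361) and with the block and pair 2 left out (0.0266). In these 5 fits the adjusted p was 0.712 to 0.867 with an estimated correlation. The NF-kB list's median shrank to -0.19 without control replicate 3 (adjusted p = 0.583 by camera). Of 30 HIF target genes, LOX and the hexokinase HK2 (-1.05, SE 0.17) fell and none rose. The list was not called (median -0.12, adjusted p = 0.462), and adjusted over the list alone, and also with the block, 2 fell and 1 rose. In the TGF-beta list, PMEPA1 (1.15, SE 0.20) and BHLHE40 (1.13, SE 0.24) rose and the receptor gene TGFBR2 fell from 425 ± 11.8 to 181 ± 45.4 CPM. The list was not called, with 7 of 24 higher and 3 lower when adjusted over the list alone, and 7 and 2 with the block (median 0.13, adjusted p = 0.438 by camera). The NRF2 list held 2 genes that fell, the aldo-keto reductases AKR1C1 (-2.02) and AKR1C3 (-1.27), which have close relatives, with 3 of 21 lower when adjusted over the list alone and 4 with the block. It was not called (median -0.19, adjusted p = 0.127), except without knockdown replicate 2 (median -0.25, adjusted p = 0.0319 by camera; adjusted p = 0.805 with an estimated correlation) and with the block and pair 2 left out (median -0.28, adjusted p = 0.0470 by camera; adjusted p = 0.867 with an estimated correlation). The NRF2 list's median shrank to -0.04 without control replicate 3 (adjusted p = 0.350 by camera). Without knockdown replicate 2, 2 rose and 6 fell in the NF-kB list, 1 rose and 2 fell in the HIF list, 6 rose and 3 fell in the TGF-beta list and 5 fell in the NRF2 list. Without another library at most 1 member rose and at most 1 fell in each of these lists.

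Few members of the lists on chromatin and development passed. None of the 25 genes of PML nuclear bodies and H3.3 deposition passed, PML not being counted, and the kinase gene HIPK2 had the smallest p (log2 fold change -0.98, adjusted p = 0.0720 by edgeR; 0.0280 with the block). The list's median was -0.06 (adjusted p = 0.438 by camera), with 0 members passing when adjusted over the list alone. Of 34 Polycomb and histone methylation genes only CBX7, a Polycomb chromobox gene, passed (0.82), with 1 higher and 1 lower when adjusted over the list alone or with the block. The median was -0.17 (adjusted p = 0.180), and -0.18, -0.32 and -0.01 in pairs 1, 2 and 3. Of 24 developmental transcription factors GATA3 fell (-1.04), with 2 higher and 2 lower when adjusted over the list alone, and 3 and 2 with the block (median -0.16, adjusted p = 0.521). Of 34 type I interferon response genes IFI44L fell, also when adjusted over the list alone, and 2 fell with the block (-2.20 for IFI44L; list median -0.05, adjusted p = 0.521 by camera). Without knockdown replicate 2, 1 gene of nuclear bodies fell, 2 developmental transcription factors fell, and 1 rose and 1 fell in each of the Polycomb and interferon lists. Without control replicate 2 and without knockdown replicate 1, 1 interferon response gene fell, and no other member of these lists passed without another library.

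Among the cell adhesion receptors ICAM1 and the protocadherin PCDH1 (1.84) rose, also when adjusted over the list alone (26 tested, median 0.06, adjusted p = 0.968 by camera). With the block 1 member, the cadherin gene CDH11, also fell (-0.71, adjusted p = 0.142 by edgeR; 0.0328 with the block). MDM2 was the only p53 target gene to change (-1.03; 25 tested, median 0.10, adjusted p = 0.521), and HK2 the only glycolysis gene (21 tested, median 0.12, adjusted p = 0.268); both counts were 1 when adjusted over the list alone. With the block, 2 p53 target genes rose and 1 fell. No member passed, over all genes or adjusted over the list alone, in the lists for G2/M (30 tested, median -0.06, adjusted p = 0.899), S phase (32 tested, median -0.03, adjusted p = 0.494), amino acid starvation and ER stress (25 tested, median 0.17, adjusted p = 0.458), YAP/TAZ targets (21 tested, median -0.13, adjusted p = 0.494) or immediate early and heat shock genes (23 tested, median 0.0015, adjusted p = 0.899 by camera). The lists for oxidative phosphorylation (39 tested) and mitochondrial mRNAs also held no member that passed, over all genes or adjusted over the list alone. With the block 1 S phase gene fell, 1 mitochondrial mRNA and 1 immediate early gene rose, and 1 rose and 1 fell in each of the stress and YAP/TAZ lists. Without knockdown replicate 2, 3 adhesion receptors rose and 1 fell, 1 rose and 1 fell in each of the p53 and glycolysis lists, 1 rose and 2 fell in the stress list, 1 rose in each of the YAP/TAZ and immediate early lists, and 1 fell in each of the S phase and oxidative phosphorylation lists. Without knockdown replicate 1, 1 adhesion receptor rose, and without any 1 of the other 4 libraries no member of these lists passed.

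Markers of other cell types gave no call. Of 7 endothelial markers tested TIE1 fell, and 2 fell and 1 rose when adjusted over the list alone or with the block (median -0.75, adjusted p = 0.199 by camera). Of 12 luminal mammary markers only GATA3 changed over all genes, 1 fell and 1 rose when adjusted over the list alone, and 1 fell and 2 rose with the block (median 0.47, adjusted p = 0.203). Without knockdown replicate 2, 2 endothelial markers fell, and 2 luminal markers rose and 1 fell. Without control replicate 2 and without knockdown replicates 1 and 3, 1 endothelial marker fell, and no other marker of these 2 lists passed without another library. Only 4 of 12 fibroblast and pericyte markers and 4 of 14 leukocyte markers were expressed enough to be kept over all libraries, so these lists were not tested there. With 1 library, or pair 2 under the block, left out, where either had enough members, neither was called (adjusted p 0.0989 to 0.742 by camera). None of the 7 lists called by camera held with an estimated correlation, where 0 lists had an adjusted and 1 an unadjusted p under 0.05. None held with fry, where 0 lists had an adjusted and 9 an unadjusted p under 0.05.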

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

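Fits with length and GC trends removed, fits with a pair left out, and the estimated correlation in fits other than the main and the blocked one, were chosen after seeing the data; the others were planned. Of the 24 genes of largest change, all kept their direction in each of these fits, which the rule of no overlap between the groups' CPM largely fixes. More genes passed with DESeq2 (614 higher, 569 lower), with no filter on low counts (593, 638), with the replicate block (636, 686), with DESeq2 and the block (898, 979), with the trends removed (486, 608) and with trends removed and the block (913, 978). All 414 genes were shared with the blocked, the unfiltered and the DESeq2 fits, and 348 with the fit without trends, which tests 13487 genes. With the block and pair 1, 2 or 3 left out, at 1 residual degree of freedom, 281, 1868 and 680 genes were higher and 381, 1931 and 996 lower. Leaving out 1 library gave 2 to 581 genes higher and 1 to 535 lower, and a PML log2 fold change of -1.27 to -1.05; each of these fits has fewer samples. The highest counts were without PML knockdown replicate 2, where 413 of the 414 genes were shared, and the lowest without control replicate 3. Other scalings, limma-voom and the stricter filter gave 334 to 426 genes. The cause of these differences was not tested.

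The 7 list calls became 0 with an estimated correlation (smallest adjusted p 0.582), 0 with fry (0.0772) and 0 with an estimated correlation and the block (0.752), and 6 to 9 in the other fits where lists were tested (the block, the stricter filter, library sizes, trends removed, and 1 library or pair 2 left out). The ribosomal list reversed without PML knockdown replicate 2 (median -0.18; 0.59 without PML knockdown replicate 1) and with the block and pair 2 left out (-0.0115), and lost its call with trends removed (0.22, adjusted p = 0.230 by camera) and with trends removed and the block (0.17, adjusted p = 0.0726). With an estimated correlation no list passed in any of the 11 fits of another filter, scaling or set of libraries or with trends removed (smallest adjusted p 0.367). Apart from the calls given in the report, the block changed no other call of PML, of the lists or of the 24 genes. Low depth limits genes near 1 CPM or below, such as HLA-DRA and CDH1.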

Other observations

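The test of library size was chosen after the result was seen, as were the genes of the next paragraph and the follow-up of the leading 3′ UTR sequences.

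Outside the lists, AREG, the amphiregulin gene, fell from 13.2 ± 2.40 to 4.99 ± 1.21 CPM (mean ± SD, n = 3; log2 fold change -1.40, SE 0.25, adjusted p = 0.0260 by edgeR's quasi-likelihood test). BTC, the betacellulin gene, had -1.27 (adjusted p = 0.112; 0.0402 with the replicate block). Among the genes that rose from low levels were KRT17, from 3.36 ± 1.02 to 9.89 ± 1.45 CPM, KRT34 from 0.91 ± 0.21 to 2.55 ± 0.22, TRIM29 from 0.13 ± 0.04 to 2.61 ± 0.61 and CRNN, the cornulin gene, from 0.10 ± 0.02 to 1.15 ± 0.30 CPM, with adjusted p of 0.0256, 0.0290, 0.0035 and 0.00651 by edgeR. At 4q13 (chromosome 4, 73740519 to 74794523, GRCh38) all 7 chemokine and EGF receptor ligand genes tested, among them CXCL8, EREG, AREG and BTC, had values below 0 with a median of -1.22, and 3 fell. MTHFD2L, the 1 other tested gene between them, had -0.01 (SE 0.26), and 19 genes within 2 Mb on either side had a median of -0.29, with 16 below 0 and 2 that fell, ADAMTS3 (-1.25) and NUP54 (-0.81, both adjusted p = 0.0486 by edgeR); G3BP2 (-0.73, adjusted p = 0.162) fell with the block (0.0445).

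Of 16345 sequences of 7 bases in 3′ UTRs, 9 went with lower values in the knockdown across 12856 genes and 6 with higher values (adjusted p under 0.05 in a linear model). Genes are not independent. In 1 permutation the smallest adjusted p of that model was 0.529, but it shuffled values freely over genes and so does not address their dependence. The 3 leading sequences that went with lower values overlap, TTCTCCA, TCTCCAA and CTCCAAA. TCTCCAA had an effect of -0.09 log2 units (adjusted p = 1.36e-10 in the linear model) and ranked 1 of all in each of the 3 pairs. It was chosen from these same pairs, so the ranks are not separate support. TCTCCAA lay in 35.1% of 191 genes that fell against 18.5% of others, with UTR length not matched. A candidate explanation is pairing of the hairpin's small RNA with these transcripts through its seed, apart from the loss of PML. The hairpin's sequence is not given in the sources used here, and a difference in an endogenous microRNA would look alike. Pairing by the control hairpin would instead lower its targets in control, and so go with higher values in the knockdown. Any of the 3 sequences lay in 55.5% of the 191 genes against 39.9% of all 12856. Pairing through them in the 3′ UTRs searched thus does not reach all of the falls. In the main fit, genes of all 12856 with any of the 3 had a median log2 fold change of -0.102, against 0.069 without. Among the 191, which were chosen for having fallen, genes with any of the 3 fell no further (median -1.345, against -1.434 without). Of the 9 sequences 2, TATTTAT (adjusted p = 0.000601 in the linear model) and CAAGGAC (adjusted p = 0.0253), do not overlap the leading ones. Thus 1 such seed does not reach all of the 9 sequences. The trends with length and GC content are argued against as the source, since 190 of 193 genes stayed lower with trends removed and the block, and an effect of PML loss itself stays open.

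For the extracellular matrix list the trends are argued against as the whole cause, as is pairing through the 3 leading sequences in 3′ UTRs. With trends removed and the block its median was -0.52 (adjusted p = 2.51e-05 by camera; adjusted p = 0.712 with an estimated correlation, where the list was not called with the block before the removal either, at 0.752), and the 19 of its 34 members without any of the 3 sequences had a median of -0.60, against -0.59 for all. Members without the 3 sequences can still hold related ones, such as TCTCCAT (adjusted p = 0.00576 in the linear model). Sites outside each gene's longest 3′ UTR were not searched, so pairing at such places stays open. Of the other lists called lower, without the 3 sequences the metastasis list had a median of -0.48 against -0.47 for all. The mesenchymal list had -0.06 over 9 of 17 members against -0.42 for all, so pairing through the 3 sequences stays open for that list. PML's longest coding transcript holds all 3 sequences, while TTCTCCA, TCTCCAA and CTCCAAA lie in 9, 14 and 5 of PML's 18 coding transcripts. They were searched anywhere in a transcript, not as 1 joined stretch, the form that a target of such a hairpin would hold. All 3 also lie in 18.1% of 8154 coding transcripts of similar length, so this decides nothing. The fall of the matrix list may therefore follow from PML loss or from pairing at places not examined. A target of the hairpin acting on these genes, or a difference between the infected populations, may also be the source. These libraries separate none of these.

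PML knockdown replicate 2 lay apart from the other libraries. Its distance to the other knockdown libraries (root mean square of log2 CPM differences, 0.704) was 1.57 times the largest distance between any 2 other libraries of a group, and 1.47 times after trends with length and GC content were removed, just under the 1.5 set beforehand. The trends held 37.3% of the variance of its deviations, but also 38.6% in control replicate 1 (2.6% to 11.7% in the others), so that share does not set it apart; the trends may be one source of the distance, but after their removal it was still the furthest (0.565 against 0.384) and the rest stays open. Library size is argued against, since knockdown replicate 1 has fewer reads (30.7 M against 32.7 M, in 1e6 reads) and lies with its group. No biological explanation was tested, as the libraries compared belong to 1 group.

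Of the 10 splits of the 6 libraries into 3 and 3, the real split gave 414 genes past the threshold of edgeR's quasi-likelihood test and the highest other gave 0. In the others 42 to 1493 genes had an unadjusted p under 0.05, against 2769 in the real split. With the block, among the 4 splits that part all pairs, the real split gave 1322 and the highest other 0, with 11 to 215 genes at an unadjusted p under 0.05 against 4324. Splits this few cannot give a share under 0.05.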
